A study of Mus musculus with 8 samples.

How the data were processed

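Gene expression was measured by RNA sequencing in 8 samples of mouse cortical progenitors taken at E15.5, 4 labelled Wildtype (Zmiz1f/f) and 4 labelled Zmiz1-KO (Zmiz1f/f;Emx1Cre). Libraries were made from total RNA with the TruSeq RNA kit, per the labels' protocols, which does not mark strand, so that reads of a gene and of an antisense partner cannot be told apart. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here.

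The authors deposited 1 table of 24972 gene rows and 8 columns, each matched to its sample by the group and number in the column name. The labels describe the values as raw counts, but the deposited values are a normalised read signal. They are fractional, and the column sums lie between 40100000 and 44200000 in every library. The most frequent low value, which stands for about 1 counted unit, ranges from 0.925 to 3.08. Between 52.7 and 86.1% of low values are whole multiples of it within 0.1, so whole counts could not be taken back. Median-of-ratios factors computed from the table were equal for all libraries at 4 digits, so the table had already been scaled in that way. No mitochondrially encoded gene has a row (0 rows), and 5164 genes are at 0 in every library. Depth is known only in relative terms: the column sum divided by the most frequent low value gives 13200000 to 20200000 for 6 libraries, 45600000 for Wildtype replicate 4 and 47300000 for Zmiz1-KO replicate 3.

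A count-based quasi-likelihood test had been planned before the data were examined. It needs whole counts and was replaced, because of the unit, by limma 3.58.1 in R 4.3.3 on log2(value + 4), with a variance trend, over the 14469 genes with a mean value of at least 30 in the 8 libraries. The pseudocount and this minimum were set after the unit was known. Fold changes are on that log2 scale, Zmiz1-KO minus Wildtype, and understate changes of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Single values were compared by exact two-sided permutation tests, whose smallest p with 4 against 4 libraries is 0.0286. The labels do not say that the samples came from separate embryos or litters, so limma and permutation p-values measure only the spread between these samples, which may be technical.

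Gene lists fixed before the data were examined (684 entries, 663 of them in the table) were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists with at least 5 tested members. Results with an estimated correlation are given beside it, and the lists called by fry are named. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Camera p-values set a list's genes against other genes. A small one at the preset correlation is therefore no measure of the spread between samples. A list score is the mean over its tested members of the log2 difference from the wildtype mean. A list of mitochondrially encoded genes was not tested for want of members, and sex-linked genes were not tested as a list.

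Named genes followed a rule fixed before the data were examined: Zmiz1 and Emx1, the 12 called genes with the largest change in each direction whose groups did not overlap, up to 4 members of every list by adjusted p, up to 2 abundant members of lists with no call, and Xist with 4 Y-linked genes. The rule named 182 genes. The text draws on 81 of them, the fixed parts and the first 2 members of every list in the rule's order. This narrowing was set after the data were examined and replaced an earlier selection that had been made with the outcomes in view. Coordinates are those of GENCODE mouse release M21 on GRCm38, which held 24490 of the table's symbols.

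The fit was tested on simulated data for this comparison, in 10 runs over 14469 genes with 100 changed genes per fold size in each run. Each gene took its residual spread from the table, and counting noise was added to it. The simulated spread was therefore larger than the table's own, and the recovered shares may differ from those of the real data. At adjusted p below 0.05 it recovered 42.3% of genes changed 2-fold and 79.6% of genes changed 4-fold, with 6.1 false calls per run. The simulated genes varied independently, so these values do not give the rate of false calls, of genes or of lists, among correlated genes. Alternatives covered scaling, filters, pseudocounts, thresholds, set tests, the replicate number as a block, robust moderation, sample weights, a sex score and a choroid plexus score as covariates, a correction for GC content and transcript length, and each library left out with the tested genes kept. Figures were drawn with matplotlib 3.10.9.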

Results

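Gene expression was measured in isolated cortical progenitors of mouse embryos at E15.5. The 4 wildtype libraries carried floxed Zmiz1 alleles without Cre. The 4 libraries labelled Zmiz1-KO also carried Emx1Cre, which is active in progenitors of the dorsal telencephalon. Zmiz1 encodes a PIAS-like transcriptional coregulator. Values are the deposited normalised read values, with column sums of 40100000 to 44200000. The column sum over the most frequent low value, a relative depth, was 13200000 to 20200000 for 6 libraries, 45600000 for Wildtype replicate 4 and 47300000 for Zmiz1-KO replicate 3.

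The targeted gene did not differ between the groups in its gene-level value. Zmiz1 (ENSMUSG00000007817, GRCm38 chromosome 14, 25459185 to 25666743, plus strand) was at 18604 ± 4780 (SD, n = 4) in wildtype libraries and 18667 ± 3187 (SD, n = 4) in libraries labelled Zmiz1-KO, with an exact permutation p of 1.0. Its log2 fold change was 0.02 ± 0.20 (SE; limma adjusted p = 0.975). Deletion of floxed exons need not lower the reads of the whole gene, so this value does not check the labels. Emx1 (chromosome 6, 85187438 to 85204462), the locus that drives Cre, was at 3669 ± 1559 (SD, n = 4) in wildtype and 1499 ± 204 (SD, n = 4) in libraries labelled Zmiz1-KO, lower in all 4 (exact permutation p = 0.0286). Its limma adjusted p was 0.174, which missed the threshold. Only libraries labelled Zmiz1-KO carried Emx1Cre. An effect of the Emx1Cre allele therefore cannot be told apart from one of Zmiz1 deletion, for Emx1 or in any comparison below.

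Which genes differ between libraries labelled Zmiz1-KO and wildtype libraries was asked across 14469 genes. In libraries labelled Zmiz1-KO, 18 genes fell and 0 rose, and several of the 18 are genes of cortical excitatory neurons. Neurod6 (chromosome 6, 55677822 to 55681263) and Bhlhe22 (chromosome 3, 18054174 to 18057517) encode basic helix-loop-helix factors of these neurons. Neurod6 went from 17140 ± 1373 (SD, n = 4) to 7207 ± 1101 (SD, n = 4), a log2 fold change of -1.26 ± 0.13 (SE; limma adjusted p = 0.0096). Bhlhe22 had a log2 fold change of -1.27 ± 0.13 (SE). Slc17a7 (chromosome 7, 45163949 to 45176142), the vesicular glutamate transporter VGLUT1, had -1.76 ± 0.21 (SE; limma adjusted p = 0.0152), and Tbr1 (chromosome 2, 61802930 to 61814114), a transcription factor of deep-layer neurons, had -1.02 ± 0.13 (SE; limma adjusted p = 0.0164). The largest changes were those of Dct, a melanin synthesis enzyme, at -2.68 ± 0.29 (SE), of Slc14a1, a urea transporter, at -2.51 ± 0.38 (SE), and of Kif26b, a kinesin family member, which went from 2231 ± 670 (SD, n = 4) to 546 ± 121 (SD, n = 4). Dct went from 922 ± 47.6 (SD, n = 4) to 151 ± 75.5 (SD, n = 4). Robo2, a Slit receptor, was at -1.22 ± 0.17 (SE) and Cntn2, a cell adhesion molecule, at -1.15 ± 0.11 (SE). The 18 genes were 2.02 to 6.40 times lower.

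By limma, 1477 genes had an unadjusted p below 0.05, 637 higher and 840 lower, and the median log2 fold change of all genes was 0.03. The groups did not overlap for 7.85% of genes, where chance gives 2.86%. The count of calls rested on single libraries: it was 0 without Wildtype replicate 2 (1084 genes at an unadjusted p below 0.05) and 0 without Zmiz1-KO replicate 4 (1064 genes), 7 without Wildtype replicate 3, 8 without Wildtype replicate 4 and 10 without Zmiz1-KO replicate 2. Without Zmiz1-KO replicate 3, which stands apart from the other libraries, 24 genes were called, 22 lower and 2 higher, and 15 of them were among the 18. The 2 higher genes, Crb2 and Ildr2, lie outside the naming rule and were named after their values were seen. Hs3st1 and Robo2 lost their calls there (limma adjusted p = 0.0534 and 0.0527). With each of the 8 libraries left out in turn, Hs3st1, Robo2 and Slc14a1 each lost the call in 7 fits. Their highest limma adjusted p values were 0.299, 0.149 and 0.307. Slc14a1 (limma adjusted p = 0.0466 with 8 libraries) kept its call only without Zmiz1-KO replicate 3 (0.0489).

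**Figure D1:**
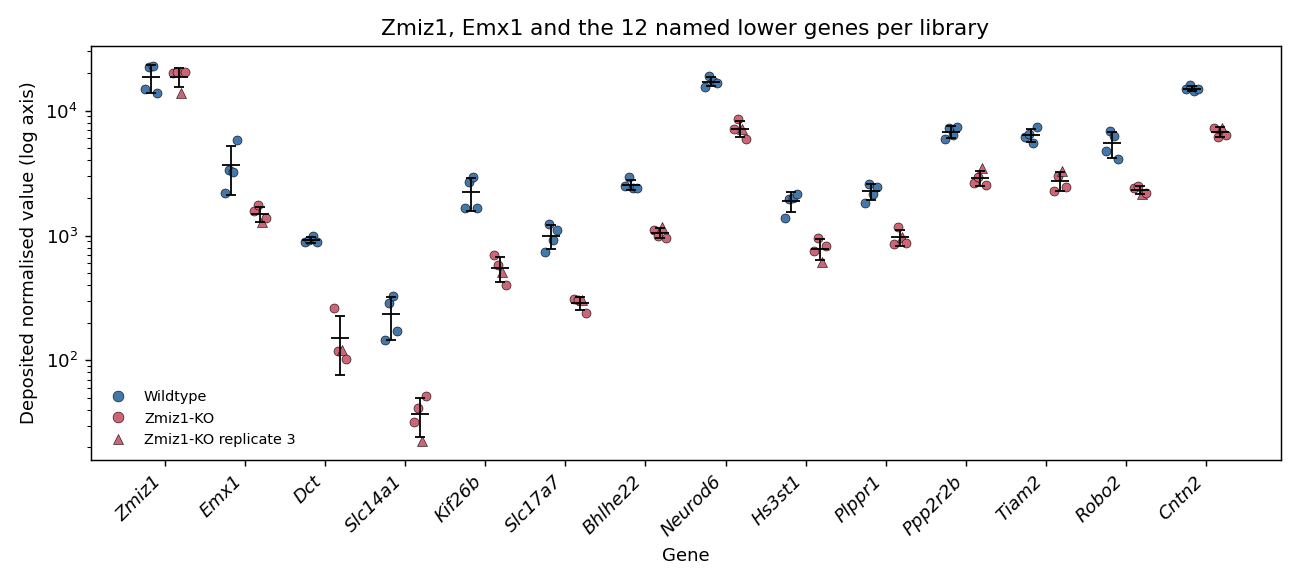
Deposited normalised value (log axis) of Zmiz1, Emx1 and the 12 named lower genes in each of the 4 wildtype (blue) and 4 Zmiz1-KO (red) libraries, with triangles for Zmiz1-KO replicate 3 and black marks for mean and SD. For the 12 lower genes every Zmiz1-KO library lies below every wildtype library, while the groups overlap for Zmiz1.

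The list of newborn excitatory neuron genes, which also holds genes common to other neurons, fell as a group. All 19 tested members had a log2 fold change below 0, with a median of -0.64 (camera adjusted p = 4.1e-15; adjusted p = 0.0396 with an estimated correlation). Past the threshold over all genes were 3 members, Cntn2, Bhlhe22 and Neurod6, and 10 were lower when adjusted over the list alone. This was the 1 list of 35 still called with an estimated correlation. Without Zmiz1-KO replicate 3 the median was -0.71 (camera adjusted p = 5.2e-13), and the adjusted p with an estimated correlation was then 0.121.

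Lists of more mature cortical neurons fell too at the preset correlation. Deep-layer neuron genes had a median log2 fold change of -0.39 over 15 members (camera adjusted p = 5.6e-05; adjusted p = 0.233 with an estimated correlation). Of them 1, Tbr1, passed over all genes and 5 were lower when adjusted over the list alone, among them Hs3st4 at -1.85 ± 0.35 (SE). The deep-layer median was -0.17 without Zmiz1-KO replicate 3 (camera adjusted p = 0.00388), with 4 lower over the list alone. Upper-layer neuron genes had a median of -0.36 over 15 members (camera adjusted p = 4.0e-04; adjusted p = 0.438 with an estimated correlation), with 0 members past the threshold over all genes and 6 lower when adjusted over the list alone. Satb2, a factor of callosal neurons, was at -1.09 ± 0.22 (SE) and Lhx2 at -0.77 ± 0.16 (SE). The upper-layer median was -0.22 without Zmiz1-KO replicate 3 (camera adjusted p = 0.0275), with 4 lower over the list alone. Synaptic transmission genes had a median of -0.37 over 22 members (camera adjusted p = 6.5e-06; adjusted p = 0.212 with an estimated correlation), with 1 past the threshold over all genes, Slc17a7, and 4 lower when adjusted over the list alone, including Slc17a6 (VGLUT2) at -0.81 ± 0.15 (SE). Without Zmiz1-KO replicate 3 the synaptic median was -0.59 (camera adjusted p = 3.3e-09), and 12 were lower when adjusted over the list alone.

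Among progenitor genes, the intermediate progenitor list fell, with a median log2 fold change of -0.31 over 14 members (camera adjusted p = 4.5e-05; adjusted p = 0.620 with an estimated correlation). No member (0) passed over all genes and 4 were lower when adjusted over the list alone. The list score was -0.86 in Zmiz1-KO replicate 3 and -0.33 to -0.087 in the other Zmiz1-KO libraries, and without replicate 3 the median was -0.15 (camera adjusted p = 0.0154). Eomes, the defining factor of these cells, went from 22639 ± 4018 (SD, n = 4) to 11028 ± 1962 (SD, n = 4), a log2 fold change of -1.04 ± 0.18 (SE; limma adjusted p = 0.0847). The radial glia list had a median of -0.19 over 16 members (camera adjusted p = 0.0225; adjusted p = 0.785 with an estimated correlation), with 0 past the threshold over all genes and 1, Hopx, lower when adjusted over the list alone. The radial glia median was -0.29 without Wildtype replicate 1 and -0.080 without Zmiz1-KO replicate 3, where 1 member was lower and 2 were higher over the list alone. It turned to 0.01 without the 2 deepest libraries (camera adjusted p = 0.811). Its call was lost without Wildtype replicate 2 (adjusted p = 0.169), Wildtype replicate 3 (0.123) or Zmiz1-KO replicate 3 (0.692).

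Cortical area patterning genes fell, with a median of -0.29 over 17 members (camera adjusted p = 0.00198; adjusted p = 0.160 with an estimated correlation). Bhlhe22 was the 1 member past the threshold over all genes, and 7 were lower and 1 higher when adjusted over the list alone. The area patterning median was -0.16 without Zmiz1-KO replicate 3, with 5 lower and 2 higher over the list alone, and -0.45 without Zmiz1-KO replicate 4. The BAF chromatin remodelling complex list had a median of -0.14 over 26 members (camera adjusted p = 0.0039; adjusted p = 0.221 with an estimated correlation), with 0 past the threshold over all genes. The 1 member lower when adjusted over the list alone was Actl6b, a neuron-specific subunit, at -1.23 ± 0.25 (SE). Without Wildtype replicate 4 the BAF median was -0.057 (camera adjusted p = 0.00464). Axon guidance genes as a list were not called (median -0.23, camera adjusted p = 0.0961), with Robo2 past the threshold over all genes and 6 lower and 4 higher when adjusted over the list alone. The axon guidance list was called without Wildtype replicate 4 (adjusted p = 0.00117) or Zmiz1-KO replicate 4 (adjusted p = 0.0312).

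Of the lists that rose at the preset correlation, none had a member past the threshold over all genes or over the list alone with 8 libraries (0 of each), while the list alone gave 10 higher choroid plexus members and 1 higher interferon member without Zmiz1-KO replicate 3. G1/S and DNA replication genes had a median log2 fold change of 0.19 (camera adjusted p = 0.0025; adjusted p = 0.785 with an estimated correlation), and the call was lost without Wildtype replicate 1 (median 0.11, adjusted p = 0.210). Without Zmiz1-KO replicate 1 the G1/S median was 0.29. G2/M genes had a median of 0.13 (camera adjusted p = 0.0205; adjusted p = 0.785 with an estimated correlation), and the call was lost without Wildtype replicate 1 (median 0.0018, adjusted p = 0.815) or Zmiz1-KO replicate 2 (0.114), 3 (0.0610) or 4 (0.0704). Without Zmiz1-KO replicate 1 the G2/M median was 0.20. Integrated stress response genes had a median of 0.80 (camera adjusted p = 5.6e-05; adjusted p = 0.709 with an estimated correlation). The score of that list was 2.23 in Zmiz1-KO replicate 3 and at most 0.57 in the other libraries, and without that library the median was 0.26 and the call was lost (adjusted p = 0.0503). Interferon response genes had a median of 0.75 (camera adjusted p = 0.0025; adjusted p = 0.354 with an estimated correlation), 0.33 without Zmiz1-KO replicate 3.

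Markers of other cell types varied between libraries. The choroid plexus and cortical hem list had a median log2 fold change of 0.45 over 16 members (camera adjusted p = 0.0283; adjusted p = 0.785 with an estimated correlation). With the sex score as covariate its direction turned, to a median of -1.12 (camera adjusted p = 1.8e-05). That fit leans on Zmiz1-KO replicate 3, whose sex score of -5.40 lay apart from those of the other Zmiz1-KO libraries. The choroid plexus score was 0.61 in Wildtype replicate 1 and 0.88, 0.59 and 0.73 in Zmiz1-KO replicates 1, 2 and 4, against -0.69 in Zmiz1-KO replicate 3 and -0.26 to -0.10 in the other wildtype libraries. The median was 0.78 without Zmiz1-KO replicate 3, with 10 of 16 members higher when adjusted over the list alone, 0.68 without Wildtype replicate 1 and 0.29 without Zmiz1-KO replicate 1, and the call was lost without any of Wildtype replicates 2 (adjusted p = 0.145), 3 (0.0818) and 4 (0.0812) or Zmiz1-KO replicates 1 (0.383), 2 (0.153) and 4 (0.234). Erythroid genes had a median of -1.05 over 9 members (camera adjusted p = 0.0025; adjusted p = 0.630 with an estimated correlation), with 0 past the threshold over all genes and 3 lower when adjusted over the list alone, against 0 without Zmiz1-KO replicate 3. Their wildtype scores ran from -1.06 to 1.25. The erythroid median was -0.35 without Wildtype replicate 1 (adjusted p = 0.0496), -1.61 without Wildtype replicate 3 and -0.62 without Zmiz1-KO replicate 2, and the call was lost without Zmiz1-KO replicate 3 (median -0.54, adjusted p = 0.114).

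**Figure D2:**
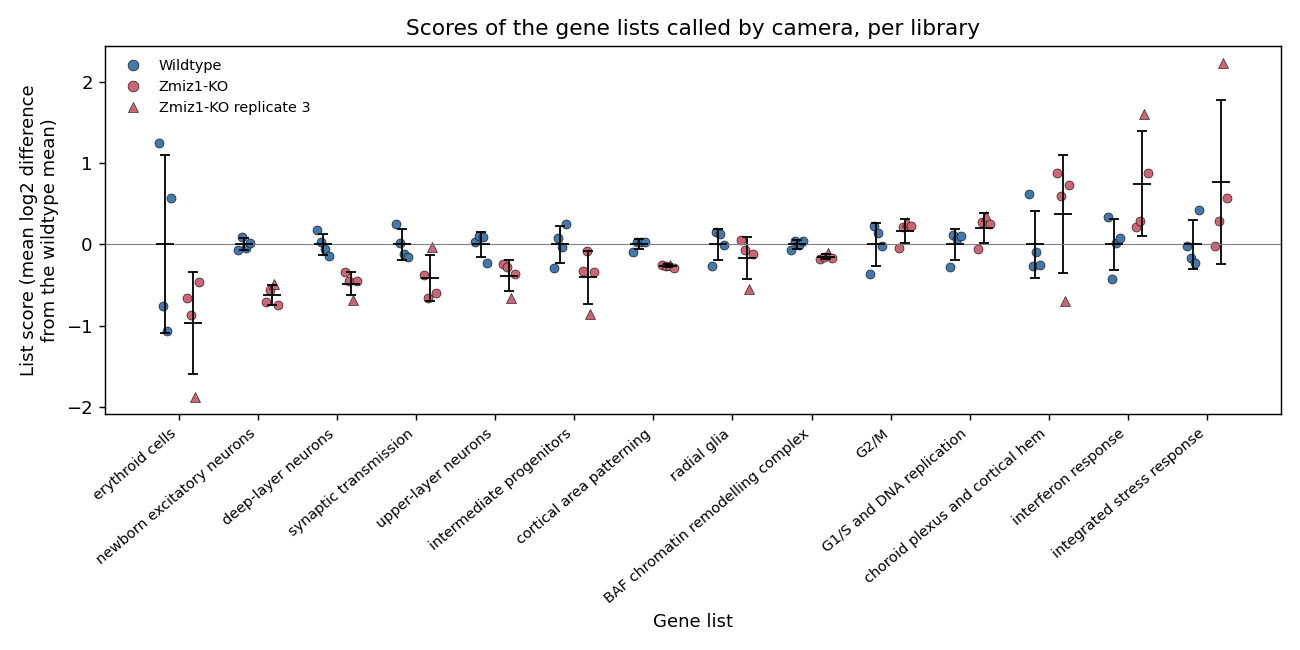
Score (mean log2 difference from the wildtype mean) of each of the 14 lists called by camera, for 4 wildtype (blue) and 4 Zmiz1-KO (red) libraries, with triangles for Zmiz1-KO replicate 3 and black marks for mean and SD. Scores of newborn excitatory neuron genes lie at -0.74 to -0.48 in Zmiz1-KO and -0.07 to 0.10 in wildtype libraries, and Zmiz1-KO replicate 3 stands apart for the integrated stress response.

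In all, 14 of 35 lists were called, 9 lower and 5 higher. Fry called 3 lists and the estimated correlation 1. The 3 were newborn excitatory neurons (fry adjusted p = 0.00155), cortical area patterning (0.0132) and the BAF complex (0.0483). Exact permutation tests of the list scores, adjusted over the 35 lists, gave a smallest adjusted p of 0.167, that of newborn excitatory neurons among others. Their smallest possible unadjusted p is 0.0286. The sex score as covariate ended the calls of G2/M (camera adjusted p = 0.149), synaptic transmission (0.459), BAF chromatin remodelling complex (0.187) and interferon response (0.110). Calls also ended with sample quality weights for G2/M and erythroid cells, quantile normalization for radial glia and the BAF complex, GC and length correction for radial glia, the first residual component for G2/M, column sum scaling for choroid plexus, and without the 2 deepest libraries for radial glia, intermediate progenitors and erythroid cells. Without Zmiz1-KO replicate 3, 22 lists were called at the preset correlation, 11 lower and 11 higher, of which 10 had also been called with 8 libraries. The estimated correlation then called 0. Fry called 5 there: newborn excitatory neurons (fry adjusted p = 0.00472), synaptic transmission (0.0204), area patterning (0.0137), the BAF complex (0.0437) and astrocytes (0.0204). Lists not called with 8 libraries, each with its median log2 fold change, were p53 targets (0.21), Wnt/beta-catenin targets (0.20), TGF-beta/BMP targets (0.16), Notch pathway (0.07), SUMO and PIAS (-0.01), autism risk genes (0.05), immediate early genes (0.14), heat shock (-0.09), hypoxia and glycolysis (-0.10), cholesterol synthesis (-0.08) and oxidative phosphorylation (-0.15). The same held for markers of subpallial cells and interneurons (0.06), Cajal-Retzius cells (0.01), oligodendrocyte precursors (0.22), astrocytes (0.21), microglia and macrophages (-0.0042), endothelial cells (0.04), pericytes and mural cells (0.43), meningeal fibroblasts (0.20) and thalamus and other brain regions (0.05).

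Zmiz1-KO replicate 3 decided the call of 12 lists of these. Without it, lists that rose were p53 targets (median 0.21, camera adjusted p = 0.0084), Wnt/beta-catenin targets (median 0.28, camera adjusted p = 0.0146), oligodendrocyte precursors (median 0.39, camera adjusted p = 0.00388), astrocytes (median 0.39, camera adjusted p = 0.00388), endothelial cells (median 0.24, camera adjusted p = 0.0084), pericytes and mural cells (median 0.74, camera adjusted p = 0.00517), meningeal fibroblasts (median 0.38, camera adjusted p = 0.0146) and thalamus and other brain regions (median 0.29, camera adjusted p = 0.0226). Lists that fell without it were heat shock (median -0.20, camera adjusted p = 0.0286), hypoxia and glycolysis (median -0.19, camera adjusted p = 0.00718), cholesterol synthesis (median -0.16, camera adjusted p = 0.00388) and oxidative phosphorylation (median -0.36, camera adjusted p = 0.000662), and none of the 12 held with an estimated correlation. With the sex score as covariate, over 8 libraries, the medians of all 12 lay on the other side of 0, and 8 were called there: oligodendrocyte precursors (median -0.95, camera adjusted p = 0.0206), astrocytes (-0.45, 0.0131), endothelial cells (-0.82, 0.0184), meningeal fibroblasts (-0.92, 0.00424), thalamus and other brain regions (-0.96, 1.0e-04), hypoxia and glycolysis (0.36, 0.0332), cholesterol synthesis (0.32, 0.0332) and oxidative phosphorylation (0.62, 0.0135). The same covariate called Notch pathway (median -0.27, 0.0184), subpallial (-1.08, 1.1e-06) and Cajal-Retzius genes (-1.16, 0.0184). Its slope leans on Zmiz1-KO replicate 3, whose sex score was -5.40, against -4.29, -4.01 and -3.72 in the other Zmiz1-KO libraries. The turns under this covariate therefore cannot be told apart from an effect of that library. Other single libraries decided calls too: without Wildtype replicate 1, cholesterol synthesis (camera adjusted p = 0.0282), oxidative phosphorylation (0.0375) and meningeal fibroblast genes (0.0496) were called, without Wildtype replicate 3 pericyte genes (0.00375), and without Wildtype replicate 4 pericyte genes (0.0127) and, lower, autism risk genes (median -0.057, 0.0363). Over the list alone, 1 member was lower among TGF-beta/BMP targets (Id4), hypoxia genes (Ndrg1) and autism risk genes (Tbr1) each, and that of Id4 was lost without Zmiz1-KO replicate 3 (limma adjusted p over the list = 0.0438 with it and 0.0930 without). The sign of the median differed from that of the test for Notch pathway, autism risk, subpallial, Cajal-Retzius, microglial and thalamic genes, and the sign of the median turned with upper-quartile scaling for Cajal-Retzius genes and with column sum scaling for SUMO and PIAS and microglial genes.

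The balance of Xist and Y-linked reads differed between the groups. Every library held reads of both Xist and Y-linked genes. The mean log2 value of Ddx3y, Eif2s3y, Kdm5d and Uty minus that of Xist was -6.05 to -5.66 in wildtype and -5.40 to -3.72 in libraries labelled Zmiz1-KO, with means of -5.86 and -4.36 (exact permutation p = 0.0286, the smallest possible). Ddx3y was at 1325 ± 523 (SD, n = 4) and 2954 ± 824 (SD, n = 4).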

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

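The tests of depth, of a label swap, of a wrong label, of Zmiz1-KO replicate 3 as the only cause, of dilution and of fewer neurons were chosen after the result was seen, and the tests of sympathoadrenal markers, sex, GC content and other splits were written before it.

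Zmiz1-KO replicate 3 stood apart from the other libraries, with a first principal component value of 109.97, against -19.2 to -12.0 in the other Zmiz1-KO libraries. Its median correlation with the other libraries was 0.898. The other Zmiz1-KO libraries had 0.969 to 0.973 and the wildtype libraries 0.961 to 0.973, against 0.898 in Zmiz1-KO replicate 3. Sympathoadrenal cells in that library may account for part of this: over 12 markers held out from the first look, its log2 value lay a median of 1.33 above the mean of the other 7 libraries, and 9 of 12 lay at least 1 above. Of these, Chgb was at 10175 (mean of the others 698), Gata2 at 3243 (123) and Th at 375 (53.9). Hand1 (4.62 against 0) lay near the floor, and Slc18a1 (44.2) lay close to the highest other library (37.2). Ddc (72.7 against 69.5) lay less than 1 above, and Chrnb4 (38.2 against 82.7) and Slc6a2 (0 against 4.74) lay below. Prph (25562 against 144) and Ret (15616 against 106) had raised the idea and are no test of it. Other cell types that may share these markers were not tested. Depth is argued against, since Wildtype replicate 4, of like depth, reached 0.415% of its distance on that component. On the newborn excitatory neuron score no wildtype library was out of place. The lowest wildtype score lay 0.490 above the highest of Zmiz1-KO replicates 1, 2 and 4, with a wildtype range of 0.169. This argues against a swap with a wildtype library on that score only. On the choroid plexus score, Wildtype replicate 1 (0.61) lay with Zmiz1-KO replicates 1, 2 and 4 (0.88, 0.59 and 0.73). Zmiz1-KO replicate 3 (-0.69) lay lowest. A swap of Wildtype replicate 1 with Zmiz1-KO replicate 3 is therefore not excluded. A wrong label with no partner cannot be told apart. The newborn excitatory neuron score of replicate 3 lay 0.409 below the lowest wildtype score, but other cells diluting a wildtype library would lower it.

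Excitatory neuron genes were lower in libraries labelled Zmiz1-KO, and the tables argue against Zmiz1-KO replicate 3 as the only cause (newborn excitatory neuron median -0.71 without it) and against GC content and length (-0.62 after correction). Dilution of all cortical cells by cells without radial glia genes is argued against for Zmiz1-KO replicates 1, 2 and 4. There the newborn minus radial glia score differed from wildtype by -0.63 (exact permutation p = 0.0286). Dilution by cells that hold radial glia genes would lower that score too, so it stays open. Astrocyte scores in those libraries were 0.36, 0.31 and 0.42, against -0.076 to 0.10 in wildtype libraries. For replicate 3 any dilution stays open, since its value of 0.063 lay within the wildtype range. Over all 4 libraries the difference was -0.45 with overlapping groups (exact permutation p = 0.114). In Zmiz1-KO replicates 1, 2 and 4 pan-neuronal scores were low too, at -0.79, -0.58 and -0.64. Cortical excitatory scores there were -0.77, -0.68 and -0.91. Fewer neurons of every kind stays open for replicates 1, 2 and 4, where the cortical excitatory minus pan-neuronal score differed by -0.12 (exact permutation p = 0.486). In replicate 3 that score was -0.98, with pan-neuronal genes at -0.013, which decides nothing where sympathoadrenal cells may add pan-neuronal transcripts, and over all 4 libraries the difference was -0.33 (exact permutation p = 0.229). Sex cannot be told apart from the group: with the sex score as a covariate the median was -0.56 (camera adjusted p = 0.0011), but the score does not overlap between groups (variance inflation 3.63), so the bound written beforehand was wrong for this design, and the genotype stays open.

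Chance could not be excluded for any count of calls. For genes, 2 of 35 splits of the 8 libraries gave at least the real 18 calls (highest other split 198), and 2 of 35 gave at least 24 without Zmiz1-KO replicate 3 (highest other 171). For lists, 19 of 35 splits gave at least 14 (highest other 23), and 4 of 35 gave at least 22 without Zmiz1-KO replicate 3 (highest other 25). The split with 198 calls points to a structure of the samples: it sets Wildtype replicate 1 and Zmiz1-KO replicates 1, 2 and 4 against the others, with 197 genes higher and 1 lower, 0 shared with the 18 called by limma (1477 at an unadjusted p below 0.05), and 9 of 16 choroid plexus and hem genes among them (list median 1.12). Clic6 was at 9722 to 11531 in those 4 libraries and at 3521 to 5261 in the others. A swap of Wildtype replicate 1 with Zmiz1-KO replicate 3 would turn the labels into that split.

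Of 246 groups of 4 values checked for a library far from its group, 26 had one, where chance gives about 12.3, and 11 of these lay in Zmiz1-KO replicate 3. In that library Zmiz1 was at 13897 (others 19960 to 20444), Dusp6 at 5373, Ebf3 at 1920.0, Clic6 at 3521, Foxd1 at 1010.3 and Ogn at 913, and scores were -0.29 for the Notch pathway, 0.49 for hypoxia and -0.35 for astrocytes. In the other Zmiz1-KO libraries, Dct (264) and Hopx (874) stood high in replicate 1, Tbr1 (3005) high in replicate 2 and Slc17a7 (238) low in replicate 4. In Wildtype replicate 1, Hes5 was at 10397, Vegfa at 7388 and Ddx58 at 295, and scores were -0.28 for G1/S and -0.093 for area patterning. Bhlhe22 was at 2920 and the endothelial score at -0.50 in Wildtype replicate 2. In Wildtype replicate 4, Ddx3y was at 544, Kdm5d at 517 and Fdft1 at 7362, and the median correlation with the other libraries was 0.961.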

How the results depend on the processing

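The pseudocounts, quantile normalization, GC and length correction, residual component, choroid plexus covariate, minimum of 100, reapplied filter, test without trend and the run without the 2 deepest libraries were chosen after seeing the data. The planned second count test with its own size factors, voom and the surrogate variable need counts and were not run. Median-of-ratios scaling moved nothing, since its factors are equal for all libraries.

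Changing one choice at a time, the newborn excitatory neuron list stayed lower and called, with a median of -0.71 to -0.48 and an adjusted p of 5.0e-18 to 0.0396. With an estimated correlation and without Zmiz1-KO replicate 3 together, the call was lost (adjusted p = 0.121). Of 2076 comparisons of named genes, 1900 kept direction and side of the threshold. With the direction kept, 85 lost the call and 76 gained one, and 15 turned sign. All 85 losses fell among the 338 comparisons of the 13 called genes, of which 253 kept the call. Of 913 comparisons of lists, 745 kept both. With the direction kept, 33 lost the call and 65 gained one. A further 70 turned sign and are counted apart, whether called or not. The 33 losses fell among the 367 comparisons of the 14 called lists, of which 332 kept both and 2 turned sign. No scaling moved the median of all genes by over 0.1.

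Against 18 genes called, 11 were called with column sum scaling, 11 with no filter on low values, 3424 with sample quality weights (1845 higher, 1579 lower), 1004 with the sex score as a covariate (869 higher, 135 lower), 53 with GC and length correction, 201 with the first residual component (99 higher, 102 lower), 29 without the 2 deepest libraries (5 higher, 24 lower), 31 with the low-value filter reapplied without Zmiz1-KO replicate 3, 34 at an adjusted p below 0.1, 4 below 0.01 and 4 without trend. Against 14 lists, 27 were called with sample quality weights, 23 with the sex score, 26 without the 2 deepest libraries, 23 with the reapplied filter, 1 with an estimated correlation and 3 with fry. Leaving out 1 library gave 0 to 24 genes (0 by limma without Wildtype replicate 2, 1084 at an unadjusted p, and 0 without Zmiz1-KO replicate 4, 1064 at an unadjusted p) and 12 to 22 lists. For the stricter threshold the lower count follows from its construction. An estimated correlation comes from the data and can lie on either side of the preset 0.01. The cause of its lower counts, and of the other changes, was not tested.

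With the replicate number as a block, limma called 0 genes (1607 at an unadjusted p below 0.05) and camera 14 lists. The labels do not say whether equal numbers pair the samples. Deviations of same-numbered libraries correlated at 0.31, 0.0063, -0.095 and -0.027, and not every library correlated best with its own number. With so few libraries these values do not decide whether the samples are paired.

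Signs that turned for upper-quartile scaling were those of Cajal-Retzius (-0.012). In the setting column sum scaling they were SUMO and PIAS (0.028) and microglia and macrophages (0.034). For mean CPM of at least 1 the values were microglia and macrophages (0.0013). Signs that turned for sample quality weights were those of Zmiz1 (-0.091), Tyrobp (0.38), autism risk genes (-0.061) and microglia and macrophages (1.17). In the setting sex score as covariate they were Zmiz1 (-0.50), Xist (0.062), Eif2s3y (-0.28), Kdm5d (-0.0050), Znrf3 (-0.079), Myt1l (0.027), Nr4a3 (0.051), Six3 (-0.50), Cspg4 (-0.62), Slc1a2 (-0.42), Clic6 (-1.06), Wnt8b (-0.75), Abcc9 (-0.21), Ogn (-1.04), Lef1 (-0.24), Notch pathway (-0.27), p53 targets (-0.19), Wnt/beta-catenin targets (-0.59), autism risk genes (-0.073), immediate early genes (-0.30), heat shock (0.26), hypoxia and glycolysis (0.36), cholesterol synthesis (0.32), oxidative phosphorylation (0.62), subpallial and interneuron (-1.08), Cajal-Retzius (-1.16), oligodendrocyte precursors (-0.95), astrocytes (-0.45), choroid plexus and cortical hem (-1.12), endothelial cells (-0.82), pericytes and mural cells (-0.58), meningeal fibroblasts (-0.92) and thalamus and other brain regions (-0.96). For quantile normalization the values were immediate early genes (-0.039), subpallial and interneuron (-0.0019), Cajal-Retzius (-0.019) and endothelial cells (-0.018). Signs that turned for GC and length correction were those of Zmiz1 (-0.13), autism risk genes (-0.12), subpallial and interneuron (-0.045), Cajal-Retzius (-0.052), microglia and macrophages (0.034) and thalamus and other brain regions (-0.043). In the setting without the 2 deepest libraries they were radial glia (0.012), autism risk genes (-0.019) and microglia and macrophages (0.53). For choroid plexus score as covariate the values were Zmiz1 (-0.046), Notch pathway (-0.0071), immediate early genes (-0.078), heat shock (0.035), oxidative phosphorylation (0.13), subpallial and interneuron (-0.053), Cajal-Retzius (-0.11), endothelial cells (-0.082), meningeal fibroblasts (-0.036) and thalamus and other brain regions (-0.22). Signs that turned for minimum mean value of 100 were those of microglia and macrophages (0.18). In the setting the low-value filter reapplied without Zmiz1-KO replicate 3 they were microglia and macrophages (0.34). Leaving out 1 library turned the sign for Cajal-Retzius (-0.10 to 0.26), Notch pathway (-0.0014 to 0.11), SUMO and PIAS (-0.080 to 0.0034), Zmiz1 (-0.10 to 0.16), autism risk genes (-0.057 to 0.12), endothelial cells (-0.12 to 0.24), immediate early genes (-0.070 to 0.25), meningeal fibroblasts (-0.10 to 0.38), microglia and macrophages (-0.30 to 0.34), oxidative phosphorylation (-0.36 to 0.091), pericytes and mural cells (-0.053 to 0.74), subpallial and interneuron (-0.10 to 0.31) and thalamus and other brain regions (-0.15 to 0.29). The cause was not tested for these. Relative depth was lowest in Wildtype replicate 1 (13200000) and highest in Zmiz1-KO replicate 3 (47300000), and which library's low genes it limits most was not tested.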

Other observations

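The tests of Zmiz1-KO replicate 3 and of sex for the p53 targets were chosen after the result was seen.

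Genes induced by p53, a stress-responsive transcription factor, had a list score of 0.24 to 0.42 in libraries labelled Zmiz1-KO and of -0.13 to 0.17 in wildtype libraries, higher in 4 of 4 (exact permutation p = 0.0286, or 0.167 adjusted over the 35 lists). Of 24 tested members, 16 had a log2 fold change above 0 and 8 below. The groups did not overlap for 2 members that were higher and 2 that were lower. The list was not called with 8 libraries (median 0.21, camera adjusted p = 0.119). Without Zmiz1-KO replicate 3 it was called at the preset correlation (median 0.21, camera adjusted p = 0.0084) and not with an estimated one (adjusted p = 0.230), so the higher median does not rest on that library. More choroid plexus and hem cells stay a possible explanation: with their score as a covariate, without that library, the median was 0.17 and missed the threshold of camera without adjustment, which meets neither bound set beforehand. Sex cannot be told apart from the group, since the sex score does not overlap between groups, and with it as a covariate over 8 libraries the direction turned (median -0.19, camera adjusted p = 0.770). That fit leans on Zmiz1-KO replicate 3, whose sex score of -5.40 lay apart from those of the other Zmiz1-KO libraries.

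The low values were whole multiples of the most frequent low value within 0.1 for 86.1% of values in Wildtype replicate 1, 85.1% in Zmiz1-KO replicate 1, 76.0% in replicate 2 and 74.3% in replicate 4, and for 52.7 to 67.1% in the other libraries. The 4 libraries with the higher shares are those with more choroid plexus genes, and those set apart by the split with 198 calls. Relative depth alone does not account for the shares: Zmiz1-KO replicate 1 (13800000) had 85.1% and Wildtype replicate 3 (14100000) had 64.1%. What sets these libraries apart, in processing or in cells, was not tested. It goes partly with the group label and may add to differences between the groups, although 0 genes of that split were among the 18 called.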
